A study of Mus musculus with 12 samples.

How the data were processed

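Hearts were taken from mouse embryos at embryonic day 17.5, from matings of mice that carried 1 disrupted copy of Slc25a1. Slc25a1 encodes the mitochondrial citrate carrier, which moves citrate out of the mitochondrial matrix. Per the labels, each sample was the total RNA of a heart, prepared with an RNeasy Micro kit and measured on the NanoString nCounter platform, which counts colour-coded probes bound to each transcript without amplification. The 12 hearts fell into 3 genotypes of 4: wild type (WT), heterozygous (HET) and homozygous knockout (KO). The labels name no litter, sex or assay batch, so none could be tested.

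The values deposited by the authors were ratios: each of the 768 probes was divided by the value of Tbp, a general transcription factor used as reference, in the same heart, so that Tbp was 1 in every heart. The panel's name, any background subtraction, the scaling to control probes and the software are not given in the sources used here. Multiplying each heart's ratios by the smallest whole number that made all of them whole within 0.01 gave probe counts, with the largest distance from a whole number below that tolerance in every heart. That multiplier was read as the Tbp count, and it ran from 276 to 433. A larger multiple of the same numbers would fit equally well, so the counts are the smallest the ratios allow. The lowest count in a heart was 5 to 9, and the total over all probes was 1285512 to 1565516. A Tbp count of 276 has a counting error of 6.02%, and 1 of 433 an error of 4.81%, which every ratio of that heart shares. Symbols were used as deposited, and 767 of 768 matched the RefSeq gene table of assembly GRCm38.p6, which served only for names.

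Values were analysed in R 4.3.3 with limma 3.58.1 as log2((count + 1) / Tbp count). The plan, fixed before the data were examined, set a pseudocount of 1 and a mean of at least 20 on the scale of counts, and the deposited values were ratios to Tbp. Both settings were therefore applied to the recovered counts, and the plan's literal reading on the ratio scale is given among the alternatives. Tbp and 72 probes with a mean count under 20 were left out, which left 695 genes. A single limma fit with 1 mean per genotype over all 12 hearts gave KO against WT, HET against WT and KO against HET. A second limma fit gave the slope over 0, 1 and 2 lost copies. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Fold changes of low genes are understated on this scale.

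In total 30 gene lists for metabolism, growth, stress and cell types were fixed before the data were examined. The 24 lists with at least 5 measured members were tested with camera in limma at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. The cardiomyocyte, endothelial, erythroid, fibroblast, cholesterol and Slc25a1-neighbour lists had 0 to 3 measured members and were not tested. The genes named were Slc25a1, the genes called, and up to 3 members with the smallest p of each list described. The list for citrate and acetyl-CoA handling is named in full. Levels per heart were also compared as mean log2 values of a list, with each heart centred on its median, by two-sided exact permutation of the hearts. With 4 hearts against 4, the smallest p such a test allows is 0.0286.

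A stromal score, the mean centred log2 value of 7 matrix and mesenchyme genes, was defined only after the main pattern of variation between hearts had been seen. These genes are Col6a1, Col6a2, Col6a3, Thbs2, Pdgfrb, Itga11 and Cyp1b1. Further lists of mast cell genes and muscle-type metabolic genes were written at the same stage.

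The analysis was tested on simulated hearts for KO against WT, with 200 of 695 genes changed in each of 20 runs. On the deposited scaling, 29.6% of changes of 0.5 on the log2 scale were called, and 87.8% of changes of 1. Median centring called 74.9% and 89.7% of these, but it also called 4.91% of the unchanged genes against 1.19% on the deposited scaling. A list of 17 genes lowered by 0.3 was found in 20 of 20 runs. Its genes were drawn independently of each other and without counting error. In the hearts the estimated correlation within a list reached 0.956 on the deposited scaling. These runs therefore do not cover lists whose genes move together. With no gene changed, median centring gave 1 call over the 20 runs and the deposited scaling gave 2. Genes were again independent and Tbp varied by counting error only, so these runs can understate false calls in real hearts. Alternatives covered the pseudocount, the filter, the scaling, the variance model, heart weights, the replicate number as a block and each heart left out. A filter on negative control probes was not run, as the 768 probes include none. Negative binomial models were not run, because the whole counts were recovered from ratios, while voom weights on them were tried as an alternative. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.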

Results

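Expression of 695 genes with a mean count of at least 20, many of them metabolic, was analysed in 12 mouse hearts of late gestation, with 4 WT, 4 HET and 4 KO hearts. Each heart came from a separate embryo, and the comparisons ask how loss of the mitochondrial citrate carrier alters metabolic gene expression in the developing heart. Total probe counts ran from 1285512 to 1565516 per heart, and the glycolytic enzyme Gapdh took 8.56% of them. Pairs of hearts of a genotype differed by more than counting error, with a chi-square per degree of freedom of 2.81 to 29.3 over 18 pairs.

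Slc25a1 followed the genotype labels. Its ratio to Tbp was 0.613 ± 0.00721 (SD, n = 4) in WT, 0.345 ± 0.0404 (SD, n = 4) in HET and 0.0985 ± 0.0182 (SD, n = 4) in KO hearts. The HET level was 56.2% of WT and the KO level 16.1%. The 3 genotypes did not overlap in any pair, and the two-sided exact permutation p was 0.0286 for KO against WT and for HET against WT, the smallest that 4 against 4 hearts allow. In limma, Slc25a1 fell by 2.62 on the log2 scale in KO against WT (SE 0.134, adjusted p = 6.23e-09) and by 0.83 in HET against WT (SE 0.134, adjusted p = 0.0138). After median centring the HET change was -0.75 with an adjusted limma p of 0.503, and the call also ended without WT replicate 1, 3 or 4 or HET replicate 2 or 4, with changes of -0.84, -0.83, -0.83, -0.78 and -0.79. The KO signal rested on 26 to 44 counts per heart, against 167 to 218 in WT. No background was subtracted here, so the HET and KO percentages may include background signal. Where the probe lies relative to the deleted part of the gene is not given in the sources used here.

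**Figure D1:**
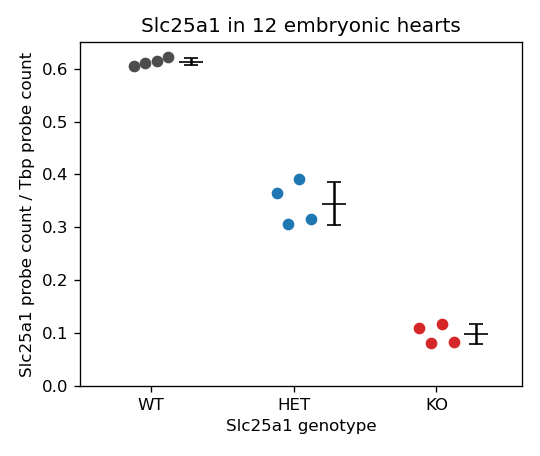
Ratio of the Slc25a1 probe count to the Tbp probe count (vertical axis) in each of the 12 hearts by genotype (horizontal axis). Points are hearts, and the bar with its whiskers beside them is the mean with SD, which falls from 0.613 in WT to 0.345 in HET and 0.0985 in KO.

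In KO against WT hearts, genes of the mitochondrial respiratory chain were lower as groups by camera, while Slc25a1 was the only gene called on the deposited scaling. All 17 measured subunits of complex I, the entry point of electrons from NADH, were below WT, with a median log2 change of -0.33. All 17 measured subunits of complexes II to V were below WT too, with a median of -0.37. The whole panel shifted down on the deposited scale, with a median log2 change of -0.13 over 695 genes in KO against WT and -0.07 in HET against WT. Relative to that median, complex I stood at -0.21 and complexes II to V at -0.25. Both lists fell in camera with the preset correlation (adjusted p = 0.00264 for each), and neither call held with an estimated correlation (adjusted p = 0.941 for each). With quantile normalization neither was called, and complex I stood at -0.04 and complexes II to V at -0.05 relative to all genes. The two-sided exact permutation p of the mean per heart was 0.114 for each list (adjusted p = 0.381). WT replicate 2 lay at -0.24 and -0.27 in these centred means, below KO replicates 2, 3 and 4. The subunits moved together, with estimated correlations of 0.956 and 0.946 on the deposited scaling, where all genes share the Tbp divisor. After median centring these correlations were 0.874 and 0.844, so the subunits are not independent observations. By name, the complex I subunits Ndufb10, Ndufb4 and Ndufb2 had log2 changes of -0.46, -0.43 and -0.39. The complex III subunit Uqcrq, the complex IV subunit Cox4i1 and the complex II subunit Sdhb had log2 changes of -0.50, -0.46 and -0.48. The SE of these 6 changes was 0.161 to 0.189 and the limma adjusted p was 0.371 for each, and no member of either list passed when adjusted over the list alone.

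The hearts also differed in a stromal score of 7 matrix and mesenchyme genes, chosen after the values were seen. These genes are also expressed by the heart's own stroma, and 2 of them belong to lists fixed earlier. Relative to the WT mean, that score was 0.67 in WT replicate 2, 0.87 in HET replicate 4 and 0.67 in KO replicate 1, the highest heart of each genotype. The same hearts had the lowest respiratory-chain score of their genotype, at -0.25, -0.23 and -0.34. As the 7 genes were chosen after the main pattern of variation between these hearts was seen, this opposition may follow from that choice. The stromal score averaged 0.21 ± 0.35 (SD, n = 4) above WT in KO hearts (two-sided exact permutation p = 0.457). With this score as a covariate, limma called 35 genes in KO against WT, 34 of them lower, and 17 of these were respiratory-chain subunits. Phgdh was the gene called higher.

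**Figure D2:**
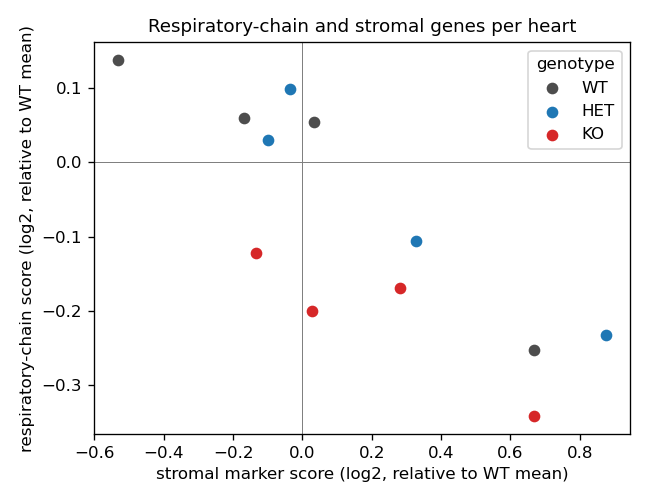
Respiratory-chain score (vertical axis, mean log2 value of 34 subunits) against the stromal score (horizontal axis, mean log2 value of 7 genes) in each heart, both median-centred and relative to the WT mean. Points are the 12 hearts coloured by genotype, and KO replicate 1 lies lowest at -0.34, while WT replicate 2 lies at -0.25. The 7 genes were chosen after the main pattern of variation between these hearts was seen.

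Genes of the tricarboxylic acid (TCA) cycle were lower in KO hearts as a group by camera, while the call of the list for citrate use needed Slc25a1 itself. The citrate and acetyl-CoA list had 7 measured members, all below WT, with a median of -0.31. Besides Slc25a1, citrate synthase (Cs) had a log2 change of -0.33, and the isocitrate dehydrogenases Idh1 and Idh2 changes of -0.31 and -0.20. The acetyl-CoA carboxylases Acacb and Acaca had log2 changes of -0.32 and -0.03, and fatty acid synthase (Fasn) one of -0.24. Acaca was 0.10 above WT after median centring, and apart from Slc25a1 no member was called (limma adjusted p = 0.371 to 0.878). The list was called in camera (adjusted p = 0.00528; adjusted p = 0.941 with an estimated correlation), and 1 member, Slc25a1, passed when adjusted over the list alone. Without Slc25a1 in the lists, 4 lists were called in place of 5, and this was the list lost, with a median of -0.28 over its other 6 members (-0.15 relative to all genes, camera adjusted p = 0.295). The TCA list shares Cs, Idh1 and Idh2 with the citrate list, and Sdha and Sdhb with complexes II to V, so the calls of these lists are not independent. In the TCA cycle and pyruvate dehydrogenase list, 22 of 23 members were below WT, with a median of -0.31. The two-sided exact permutation p of its centred mean per heart was 0.143 (adjusted p = 0.381). WT replicate 2 lay at -0.21, below KO replicates 2 (-0.09), 3 (-0.14) and 4 (-0.08). That list fell in camera (adjusted p = 0.0147) but not with an estimated correlation (adjusted p = 0.941), with no member passing when adjusted over the list alone, and its member Mpc2, a subunit of the mitochondrial pyruvate carrier, had a log2 change of -0.47. In the mTOR, AMPK and insulin signalling list, 30 of 31 members were below WT on the deposited scaling, as were 24 of 25 housekeeping candidates. The mTOR list stood only 0.05 below the median of all genes, as did the housekeeping list. The mTOR list fell in camera at an adjusted p of 0.0219 (adjusted p = 0.941 with an estimated correlation), and the housekeeping list was not called (camera adjusted p = 0.126). The PI3-kinase subunits Pik3r3 and Pik3cb had log2 changes of -0.39 and -0.43, and the AMPK subunit Prkag1 one of -0.34. The mTOR list's call ended without WT replicate 4 (-0.04 relative to all genes) or KO replicate 1 (-0.04), and also at a mean count of 50, with housekeeping centring, quantile normalization or the stromal covariate and without the 3 hearts highest in stromal score, and the TCA list's call without KO replicate 1 (-0.12).

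By fry, 1 list was called in KO against WT, the citrate list (adjusted p = 0.0113), which holds the deleted gene and had an adjusted p of 0.353 by fry without it, with an adjusted p of 0.353 for complex I, complexes II to V, the TCA list and the mTOR list. The other 19 lists were not called in KO against WT by camera. In fatty acid oxidation, 11 of 12 members were below WT, or 9 of 12 after median centring, with a median of -0.12 relative to all genes. Its members Cd36, a fatty acid transporter, and the nuclear receptor Pparg had log2 changes of -0.59 and -0.64, and Hadh, an enzyme of beta oxidation, one of -0.33. Of the 12 members, 2 were lower when adjusted over the list alone, though the limma adjusted p over all genes was 0.371 for each of the 3 named. In glycolysis and glucose transport, 21 of 25 members were below WT, or 16 of 25 after median centring, with a median of -0.11 relative to all genes, and the muscle-type enzymes Eno3 and Pgam2 had log2 changes of -0.43 and -0.36. Tigar, which lowers fructose 2,6-bisphosphate, had a change of -0.47. In the opposite direction, all 5 amino acid transporters were above WT, with a median of 0.18 relative to all genes, and Slc7a11, Slc7a5 and Slc3a2 had log2 changes of 0.16, 0.08 and 0.06. That list was called after median centring (camera adjusted p = 0.0348; adjusted p = 0.364 with an estimated correlation). Scd1, a fatty acid desaturase, had a log2 change of 0.36 in KO hearts, and heme oxygenase Hmox1 one of 0.35. Medians relative to all genes were 0.12 for targets of the stress factor ATF4, 0.11 for leukocyte markers, 0.11 for p53 targets and 0.07 for DNA repair. They lay between -0.05 and 0.03 for autophagy, cell cycle, chromatin enzymes, lipid synthesis, glutamine metabolism, housekeeping genes, hypoxia targets, mitochondrial biogenesis, NRF2 targets, nucleotide synthesis, the pentose phosphate pathway and one-carbon metabolism.

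Centring each heart on its median narrowed the spread between hearts, from a median residual SD of 0.207 to 0.139 on the log2 scale. On that scaling limma called 3 genes in KO against WT, 1 higher and 2 lower. Phgdh, the first enzyme of serine synthesis, rose by 0.58 (SE 0.0799, adjusted p = 0.00564). Itga1, a collagen-binding integrin subunit named after its values were seen, fell by 0.43 (SE 0.0795, adjusted p = 0.0456). Phgdh stayed called without any single heart (adjusted p = 0.00198 to 0.0318), whereas Itga1 kept its call without KO replicate 4 (adjusted p = 0.0252) and lost it without any of the other 11 hearts (adjusted p up to 0.193), with changes between -0.49 and -0.36 over the 12 omissions. In simulations with many changed genes this scaling called 4.91% of the unchanged ones. Cd36 missed the threshold at -0.46 (limma adjusted p = 0.0973). On the deposited scaling Phgdh had a log2 change of 0.45 with a limma adjusted p of 0.334. Its fellow serine enzyme Psph lay 0.31 below WT on that scaling, and the aminotransferase Got1 0.38 below.

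**Figure D3:**
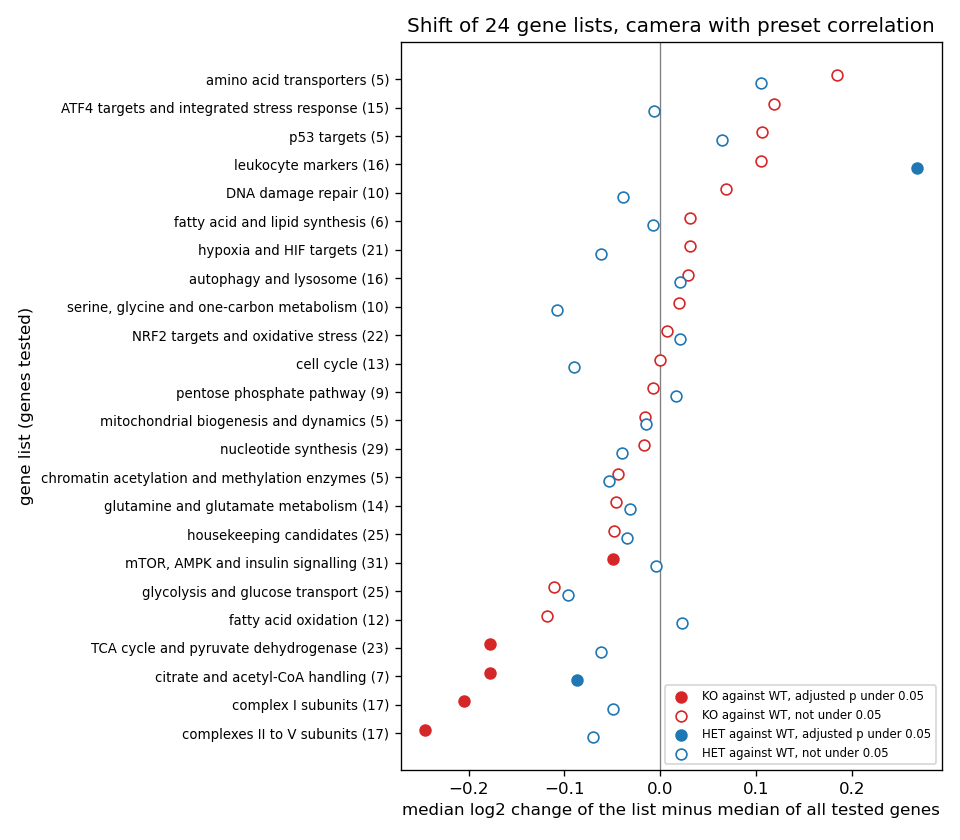
Median log2 change of each of the 24 tested gene lists minus the median of all 695 tested genes (horizontal axis), for KO against WT and HET against WT on the deposited scaling. Filled points passed camera at an adjusted p under 0.05, and complexes II to V lie lowest in KO at -0.25 while leukocyte markers lie highest in HET at 0.27.

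In HET against WT hearts, leukocyte markers were higher and no gene other than Slc25a1 was called. Of 16 leukocyte markers, 13 were above WT, with a median log2 change of 0.20. The protease Gzma, the mast cell receptor subunit Ms4a2 and the pan-leukocyte phosphatase Ptprc had changes of 0.44, 0.35 and 0.30, on mean counts of 28.0, 51.8 and 80.7. The list rose in camera (adjusted p = 0.000576) but not with an estimated correlation (adjusted p = 0.22), and the two-sided exact permutation p of its mean per heart was 0.2. The heart with the highest stromal score in each genotype also had that genotype's highest leukocyte score, at 0.26 in WT replicate 2, 0.46 in HET replicate 4 and 0.37 in KO replicate 1, but HET replicate 3 had a leukocyte score of 0.37 at a stromal score of -0.04, and HET replicate 2 one of 0.04 at 0.33. With the stromal score as a covariate the leukocyte list stood at 0.12 relative to all genes, against 0.27 without it, and was not called. The citrate and acetyl-CoA list was called lower in camera (adjusted p = 0.0265; adjusted p = 0.779 with an estimated correlation), with all 7 below WT at a median of -0.16. Fasn had a log2 change of -0.19 and Idh1 one of -0.16, and without Slc25a1 this list was no longer called. Complexes II to V and complex I were not called by camera (adjusted p = 0.0885 and 0.108), with medians of -0.07 and -0.05 relative to all genes. Sdhb, Uqcrq and Ndufa12 had log2 changes of -0.22, -0.20 and -0.19 in HET hearts. Shmt2 and Psat1, enzymes of serine and one-carbon metabolism, had changes of -0.26 each, and the mitotic regulators Cdc20 and Bub1b changes of -0.23 and -0.25. The glycolytic enzyme enolase (Eno1) had a log2 change of -0.31. Apart from Slc25a1 the limma adjusted p was 0.871 for each HET gene named, and 22 genes had an unadjusted p under 0.05. The 2 called lists became 9 without WT replicate 2, 6 without HET replicate 3, 4 without HET replicate 1, 1 without WT replicate 1 or HET replicate 4 and 0 without WT replicate 4.

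In KO against HET hearts 3 genes were called, 1 higher and 2 lower. Phgdh rose by 0.61 on the log2 scale (SE 0.114, limma adjusted p = 0.0301), from a ratio of 0.695 ± 0.0329 (SD, n = 4) to 1.07 ± 0.115 (SD, n = 4). All 4 KO hearts lay above all 4 HET hearts. The leptin receptor Lepr fell by 0.87 (SE 0.17, limma adjusted p = 0.032), with all 4 KO hearts below all 4 HET hearts on the deposited scaling but KO replicate 1 (-1.30) above HET replicate 3 (-1.37) after median centring, and Slc25a1 fell by 1.79 (SE 0.134, limma adjusted p = 1.15e-06). Leaving out any of the 4 HET hearts, KO replicates 2, 3 or 4 or WT replicate 4 left 1 gene called, Slc25a1, with adjusted p up to 0.143 for Phgdh and for Lepr. Over all 29 alternatives the change of Phgdh ran from 0.286 to 0.746 and lost its call in 10. That of Lepr ran from -1.05 to -0.27 and lost its call in 15. After median centring Phgdh and Slc25a1 were called and Lepr was not (limma adjusted p = 0.218). Relative to a median of -0.08 over all genes, camera called 4 lists higher in KO against HET. Above HET were 11 of 15 ATF4 targets (adjusted p = 0.00161), 13 of 21 hypoxia targets (adjusted p = 0.0129), 11 of 13 cell cycle genes (adjusted p = 0.0137) and 5 of 10 one-carbon genes (adjusted p = 0.0231). The ATF4 and one-carbon lists share Phgdh, Psat1, Psph and Shmt2, so their calls are not independent. Camera was not run on either list without Phgdh. Camera called 3 lists lower, with 17 of 17 complex I subunits (adjusted p = 0.0129), 16 of 17 subunits of complexes II to V and 7 of 7 citrate genes (adjusted p = 0.0231 for each) below HET. The citrate list holds the deleted gene, and without Slc25a1 its adjusted p was 0.777 and 6 lists were called in place of 7. After median centring 6 lists were called higher and 4 lower, and none with an estimated correlation. On the deposited scaling the adjusted p with an estimated correlation was 0.932 for each of the 7 lists called there. Fry called none in KO against HET (lowest adjusted p = 0.412) or in HET against WT (lowest adjusted p = 0.649).

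Along the number of lost copies, Slc25a1 was the only gene with a called linear trend, and 88 genes had an unadjusted p under 0.05 in limma. Across the 694 other genes, the HET and KO changes against WT correlated with r = 0.63 and a covariance of 0.0233. Genes are not independent replicates, and both comparisons share the WT hearts. With unchanged groups simulated against shared controls, r had a median of 0.48 (95% of 100 draws between -0.20 and 0.91) and the covariance a median of 0.0122. With the WT hearts split between the comparisons, r averaged 0.21 and the covariance 0.00969 over 6 splits.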

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

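The tests of stromal tissue, of the reference gene and of the ATF4 programme were chosen only after the results they bear on had been seen, and so were the stromal score, its use as a covariate and the split tests that leave out Slc25a1. Among 162 groups of 4 values, 3 held a heart far from the rest, where chance gives about 1 in 20, or 8.1. The Idh1 ratio was 4.31 in KO replicate 4 against 3.39 to 3.54 in the other KO hearts. The Pparg ratio was 0.0845 in WT replicate 2 against 0.146 to 0.156 in the other WT hearts. The Cd8b1 ratio was 0.193 in HET replicate 3 against 0.101 to 0.105 in the other HET hearts.

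Respiratory-chain genes were lower in KO hearts, with 33 of 34 subunits below WT and a median of -0.21 after median centring. A shift of the reference gene Tbp moves all genes alike and cannot by itself leave these genes at -0.21 relative to the rest. If the score measured stroma without error, more stromal tissue in the KO hearts would have taken the change to near 0 with the score in the model. The respiratory-chain score changed from -0.21 (SE 0.1) to -0.14 (SE 0.0356), below 0 by more than 2 SE (exact permutation of the hearts, p = 0.0286 over 35 splits, the smallest they allow). That change was known before the prediction was written. Within genotypes the 2 scores correlated with r = -0.945. The 7 stromal genes were chosen after the main pattern of variation between these hearts was seen. This correlation, the smaller SE and the permutation p with the score may partly follow from that choice. An imperfect stromal score would leave part of the effect of stroma unadjusted, so the test cannot decide whether stroma is the whole cause. Stroma, an effect of genotype, a difference in muscle maturity and the share of a cell type that the 7 genes do not mark may each remain. Without the score the same permutation gave p = 0.114, so chance was not excluded for the change itself. With quantile normalization neither respiratory-chain list was called. Subunits such as Cox6a1 and Cox5a were among the probes with the highest counts, at 2.33% and 2.19% of the total. Whether the change depended on the count level of a gene was not tested.

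Chance cannot be excluded for the 5 lists called in KO against WT, because 7 of 35 splits of the same hearts called as many and the highest other split called 7. The stromal covariate gave 35 genes, or 34 besides Slc25a1, in the real split and at most 1 in the others, so 1 of 35 splits, the real one, gave as many. The splits kept the score fixed and do not account for its choice after the values were seen. They do not by themselves exclude chance for this count. Heart quality weights gave 166 genes, but 11 of 35 splits gave as many and the highest other gave 373, so chance was not excluded for that count. The gene called on the deposited scaling is Slc25a1, which defines the genotypes, so that 1 of 35 splits, the real one, called it and the highest other called 0 says nothing of other genes. After median centring 3 genes were called, 2 of them besides Slc25a1, and 1 of 35 splits reached either number, with 1 in the highest other. The real split led by a margin of 1 gene, and Itga1, 1 of these 2, lost its call without any of 11 hearts. As the split tests were not adjusted for their number, chance was not firmly excluded for that count.

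Phgdh was higher in KO than in HET hearts, at 0.66 after median centring. A raised ATF4 programme, a stress response that drives serine synthesis, is a candidate explanation. The other 14 ATF4 list members had a mean KO minus HET change of 0.10 (SE 0.0392), 11 of them above 0 in a range from -0.22 to 0.37, and an exact permutation p of 0.0571. Members thus went both ways, and a rise of Phgdh alone cannot be told apart from a rise shared by some of the list with 4 hearts per genotype.

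In KO against HET 3 genes were called, 2 of them besides Slc25a1, and 1 of 35 splits reached either number, with 1 gene in the highest other. The real split led by a margin of 1 gene, and leaving out any of 8 single hearts left 1 gene called, Slc25a1. The split tests were not adjusted for their number, so chance was not firmly excluded for that count. In HET against WT and along the trend the 1 gene called was Slc25a1, whose level separates WT from HET hearts without overlap (exact permutation p = 0.0286), so its fall does not rest on these counts. As counts of genes, chance was not excluded for either, since 5 of 35 splits called at least 1 gene in HET against WT and 6 of 100 drawn assignments did so for the trend, with 8 in the highest other of each. Chance was not excluded for the 2 HET lists, met by 14 of 35 splits with 8 in the highest other. The 7 lists in KO against HET were reached by 1 of 35 splits, the real one, with 6 in the highest other, but with Slc25a1 left out 3 of 35 splits reached the real 6 lists, with 6 in the highest other, so chance was not excluded for these.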

How the results depend on the processing

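Settings on the ratio scale, voom, the stromal covariate, the omission of the 3 hearts with the highest stromal scores, lists without Slc25a1 and the refits after median centring were added after seeing the data; the cause of a change was not tested. Genes called in KO against WT numbered 3 with median centring, 4 with housekeeping centring or quantile normalization, 166 with heart quality weights, 35 with the stromal covariate, 34 with that covariate and median centring, 2 without the 3 hearts and 10 with voom. Without any single heart it stayed at 1. The count of 3 after median centring became 34 with the covariate, 38 without the 3 hearts and 2 to 3 without any single heart. In HET against WT the count was 0 with either centring, on the ratio scale with its filter, with the covariate and centring, without the 3 hearts and with voom, 4 with heart weights, and 0 to 1 without any single heart. In KO against HET it was 5 with an eBayes trend, 7 with heart weights, 0 on the ratio scale with its filter (53 genes tested), 53 with the covariate, 36 with the covariate and centring, 8 with voom and 1 to 3 without any single heart. Trend calls numbered 2 with housekeeping centring, quantile normalization or the covariate on either scaling, 182 with heart weights and 14 with voom.

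The KO fall of Slc25a1 passed under all 30 alternatives, from -2.71 to -0.55. Its HET change lost its call with median centring (-0.75), housekeeping centring (-0.73), the ratio scale with its filter (-0.26), the covariate with centring (-0.83), voom (-0.70) and the omission of the 3 hearts (-0.79); single omissions gave -0.90 to -0.78, and the call ended without WT replicates 1 (-0.84), 3 (-0.83) or 4 (-0.83) and HET replicates 2 (-0.78) or 4 (-0.79). KO against HET lost its call only on the ratio scale with its filter (-0.29). Lists called in KO against WT numbered 0 with quantile normalization or an estimated correlation and 4 to 7 without any single heart. In HET against WT they numbered 4 at a mean count of 50, 8 with median and 9 with housekeeping centring, 1 with quantile normalization or without Slc25a1, 0 with the covariate or an estimated correlation, 10 without the 3 hearts and 0 to 9 without any single heart. Lists in KO against HET were refitted with median centring, an estimated correlation, fry and without Slc25a1 only. The correlation of HET and KO changes ran from 0.45 to 0.76.

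Of 1464 refits of the named genes other than Slc25a1, 82 were of changes that were called, of which 46 kept and 36 lost the call. Of the 1382 refits of changes not called, 1305 stayed so with the same sign, 61 gained a call and 16 changed sign. In KO against WT, Acaca was 0.10 with median centring, 0.14 with housekeeping centring, 0.12 with quantile normalization, 0.23 with voom, 0.00069 and 0.0763 with the covariate as deposited and centred, 0.0167 without the 3 hearts, and -0.109 to 0.0182 over single omissions, above 0 without WT replicate 1 (0.00331), WT replicate 4 (0.0123) or KO replicate 1 (0.0182). Idh2 was 0.0617 and Fasn 0.0175 with voom, and Slc7a11 was -0.12 with heart weights. Over single omissions Slc7a5 ran from -0.0379 to 0.150, below 0 without WT replicate 3 (-0.0379) or KO replicate 2 (-0.0057), and Slc3a2 from -0.0176 to 0.113, below 0 without WT replicate 3.

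Hearts with the same number in the labels did not deviate together: 12 pairs had correlations from -0.51 to 0.36, 5 of them over 0.1, and 3 of 12 hearts correlated best with their own number. With the replicate number as a block, the calls were 1 in KO against WT, 1 in HET against WT, 2 in KO against HET and 1 for the trend.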

Other observations

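The lists of mast cell genes and of muscle-type metabolic genes, and all tests in this part, were chosen after the values were seen. The mean of 5 mast cell genes, whose highest member had a mean count of 329.6, lay 0.41 ± 0.26 (SD, n = 4) above WT in HET hearts (two-sided exact permutation p = 0.143) and 0.20 ± 0.53 (SD, n = 4) above WT in KO hearts (exact permutation p = 0.543). Of these genes, 2 also belong to lists fixed earlier. The mean of 6 muscle-type metabolic genes lay at -0.26 ± 0.11 (SD, n = 4) in KO hearts relative to WT (exact permutation p = 0.0857) and at -0.08 ± 0.15 (SD, n = 4) in HET hearts (exact permutation p = 0.543). Of these 6 genes, 5 belong to lists fixed earlier.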
